A study of Mus musculus with 6 samples.

How the data were processed

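RNA came from CD31-positive, CD45-negative cells sorted from collagenase-digested mouse spleens, per the labels' protocols, with 3 wild-type and 3 Stab1 knockout samples. Complementary DNA was made with an ultra-low-input SMART-Seq kit and libraries with Nextera XT, a combination that does not mark strand, and the series' design text names a HiSeq instrument. The submitters' processing notes name STAR 2.5.2b, Subread, edgeR, limma and the mm10 build, without their order or settings. The authors deposited gene expression as RPKM for 23337 genes and 6 libraries, per the file headers. The authors also deposited log2 fold changes and their p-values, raw and adjusted, in a table of 13742 genes and in lists of higher and lower genes, per the file headers. The deposited columns carry a genotype and a number that does not match the labels' replicate numbers, so each column was assigned to its genotype only and is called by its own number. No column of per-sample values was left without a group.

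RPKM are not counts, so the fit was made on log2 values. The planned count tests, set for deposited counts or reads recovered from CPM or RPM, were left out, and of tests on recovered reads only voom was run. For 17676 of the 17683 genes above 0 (99.96%), each library's value was a whole multiple of 1 read's worth within a tolerance of 0.001, which gave the reads per gene and the depth of each library, 37154836 to 47982555 reads. The deposited values were scaled beyond depth by factors of 0.977 to 1.035. Depth of this size leaves little counting error for genes at several RPKM, so the spread between libraries sets the precision. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 29.8 to 95.5 over the 6 pairs within groups), so no pair was treated as copies of 1 library; separate preparations of the same RNA would differ by more than that too, so this does not show separate samples. Within groups, log2 values correlated at 0.974 to 0.990, and between groups at 0.964 to 0.985.

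Genes with at least 1 RPKM in at least 3 of the 6 libraries were kept, which left 11035. Values of log2(RPKM + 0.5) were fitted on genotype with limma 3.58.1 in R 4.3.3 (moderated variances with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Stab1 was also tested by exact permutation of the group means. Before the data were examined, 45 gene lists were fixed (endothelial identity and function, signalling, immune response, cell biology, RNA quality and markers of other cell types). The 36 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list moves on balance one way. No call held with an estimated correlation (lowest adjusted p 0.446) or in fry (0.0553). Lists with an estimated correlation near 0, such as complement and coagulation (-0.013), lost their call too, so its loss does not show that a list's genes vary together. List entries were matched by symbol (922) or by a unique older symbol (24), and 41 were not matched, among them the mitochondrially encoded genes, which were not analysed here.

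The genes named were fixed by rule before the data were examined. They are Stab1 and Stab2, the 12 greatest rises and 12 greatest falls among called genes whose groups do not overlap (predicted genes and pseudogenes left out), up to 4 members of smallest p per list, and Madcam1, Vcam1, Icam1, Cxcl13, Ccl21a and Ccl19. Other names, such as those of genes beside Stab1 or in dense stretches of chromosomes, the further cholesterol genes and Ptprc, were chosen after their values were seen. Some genes of these lists are not reported here.

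Coordinates came from the RefSeq annotation of GRCm38, matched for 23092 genes, and transcript length and GC content from the longest GENCODE M21 transcript. Called genes were counted within 20 Mb of Stab1 and in 10 Mb bins, where a bin counted as enriched with at least 3 calls and an adjusted Fisher p under 0.05. Calls with another call within 1 Mb were compared with 10000 permutations of the calls over tested genes. GC and length trends were removed by a loess fit of each library's deviations from the gene means on GC content and log2 length. Positions and figures used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.

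The fit was tested on simulated data, with reads for 10879 genes drawn from the observed means, depths and spread within groups. It recovered 18.4% of genes changed 1.5-fold, 63.3% of those changed 2-fold, 91.8% of those changed 3-fold and 96% of those changed 4-fold, and 5.67% of its calls were false. Of 20 random lists in the same simulation, 0 passed. Each gene was drawn there independently and without a GC trend, so this does not cover lists whose genes vary together between libraries. Alternatives fixed beforehand were other pseudocounts, filters and scalings, robust variances, library quality weights, other thresholds and the removal of each library. GC and length correction, limma's voom on the recovered reads and removal of chromosome stretches rich in calls were added after the data were seen, as was a block on the numbers in the column names, which the ranges over 17 alternatives leave out.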

Results

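Endothelial cells were sorted as CD31-positive, CD45-negative cells from collagenase-digested spleens of wild-type mice and of mice lacking Stab1. Stab1 encodes stabilin-1, also called Clever-1, a scavenger receptor of sinusoidal and lymphatic endothelium and of some macrophages. The study asked how this receptor bears on contacts between the spleen vasculature and lymphocytes. RNA-seq gave 6 libraries, 3 wild type (WT 1, WT 3 and WT 4) and 3 knockout (KO 2, KO 3 and KO 4), all labelled C57BL/6. The labels do not state that each library came from its own animal, so p-values measure only the spread between these libraries. Depth, recovered from the deposited RPKM values as reads counted to genes, was 37154836 in WT 1, 46727662 in WT 3, 41909728 in WT 4, 46372046 in KO 2, 47982555 in KO 3 and 37771361 in KO 4. Levels are RPKM as mean ± SD (n = 3 per group), and log2 fold changes (knockout minus wild type) are on the log2(RPKM + 0.5) scale, which understates the change of low genes.

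The targeted gene was examined first. Stab1 (gene ID 192187, chromosome 14, 31139017 to 31168651, GRCm38) was at 21.6 RPKM in WT 1, 43.6 in WT 3 and 31.4 in WT 4, and at 2.32 in KO 2, 2.62 in KO 3 and 2.49 in KO 4. The log2 fold change was -3.40 ± 0.22 (SE), with an adjusted p of 7.15e-05 in limma. The knockout libraries kept 812 to 1063 reads over the gene, against 7212 to 17625 in wild type. An exact permutation test of the means over the 20 assignments gave a two-sided p of 0.1, the smallest that 3 against 3 libraries allow. Stab2, the paralogous scavenger receptor of sinusoids, was at 167 ± 48.7 in wild type and 174 ± 13 in knockout (log2 fold change 0.10, adjusted p = 0.806). Both genes beside Stab1, chosen after their values were seen, rose. Nt5dc2 went from 25.5 ± 1.23 to 81.6 ± 8.74 (log2 fold change 1.65, adjusted p = 7.15e-05) and Nisch from 41.0 ± 11.3 to 92.5 ± 6.61 (log2 fold change 1.2, adjusted p = 0.0107), and the call of Nisch was lost without KO 3 (adjusted p = 0.0607) and with no filter on low values (0.0824). The annotated ends of Nt5dc2 and Stab1 overlap, and the library kit does not mark strand, so reads in the overlap cannot be assigned.

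**Figure D1:**
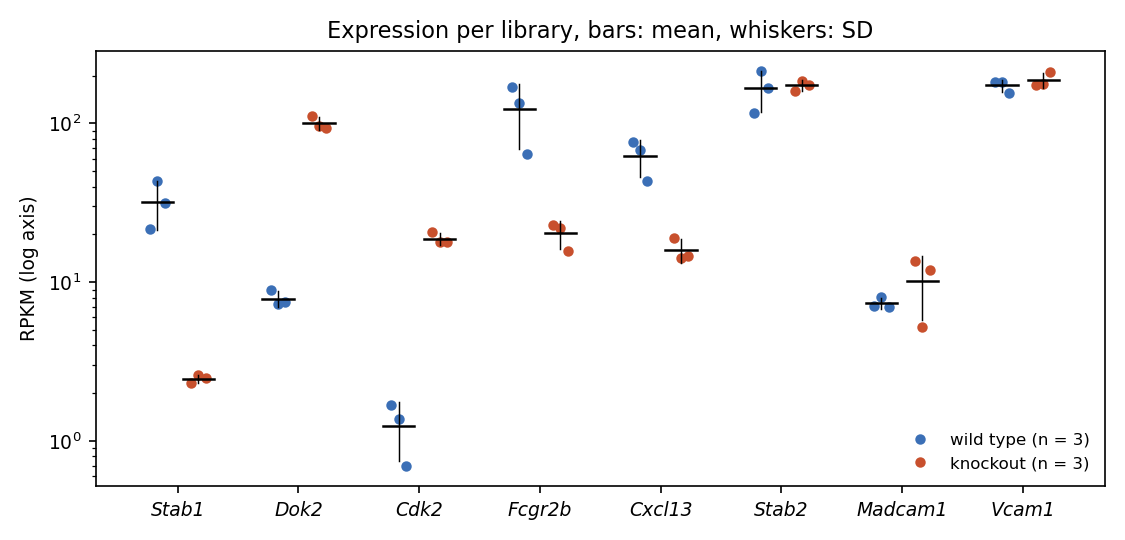
RPKM of 8 genes on a log axis in each of the 6 libraries, with the group mean as a bar and the SD as a whisker (n = 3 per group). Stab1, Fcgr2b and Cxcl13 were lower in every knockout library than in every wild-type library, Dok2 and Cdk2 were higher, and Stab2, Madcam1 and Vcam1 did not pass the test.

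Loss of Stab1 was set against wild type across all genes. Among genes above 0 in both groups, the greatest rises were those of Dok2, an adaptor protein gene (chromosome 14, 70765889 to 70778494), from 7.90 ± 0.895 to 101 ± 9.86 (log2 fold change 3.59 ± 0.12 SE), and of Cdk2, a cell cycle kinase gene (chromosome 10, 128697938 to 128705051), from 1.25 ± 0.505 to 18.8 ± 1.70 (3.51 ± 0.22 SE). Ifi202b (chromosome 1, 173962569 to 173982844), an interferon-inducible gene known to differ in expression between inbred strains, was listed at 0 in all 3 wild-type libraries and at 14.4, 13.7 and 20.5 RPKM in KO 2, KO 3 and KO 4. The amino acid transporter gene Slc7a8, also on chromosome 14, went from 15.5 ± 2.82 to 61.6 ± 7.27 and Olfml2b, a secreted matrix protein gene, from 18.3 ± 4.0 to 69.3 ± 8.40. Rtn1, Pnp2, Fbp1, Abhd1, Fam126a, Kcnj14 and Slc15a2 completed the 12 greatest rises, with log2 fold changes from 1.65 to 2.52. The call of Slc15a2 was lost without KO 2, KO 3 or KO 4 (adjusted p at most 0.117) and with no filter on low values (0.134), and it reached 0.188 over all alternatives. After Stab1, the greatest fall was that of Pla1a, a phospholipase gene (chromosome 16, 38396117 to 38433191), from 81.9 ± 7.63 to 10.4 ± 0.850 (log2 fold change -2.92 ± 0.11 SE). The netrin receptor gene Unc5a fell from 7.28 ± 2.17 to 0.567 ± 0.209, and Fcgr2b, the inhibitory Fc receptor gene (chromosome 1, 170960558 to 170976071), from 123 ± 54.0 to 20.3 ± 4.0, a call lost with no filter on low values (adjusted p = 0.0603). Zfp367, Pttg1, Ifi204, Pcp4l1, Rab6b, Cxcl13, Tmem180 and Ang made up the rest, with log2 fold changes from -2.45 to -1.76. Ifi202b, Ifi204 and Pnp2 have close copies in the genome, so their levels are uncertain.

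In all, 214 of 11035 genes tested passed an adjusted p of 0.05, 74 higher and 140 lower in knockout, and 117 of them changed at least 2-fold (30 higher, 87 lower). Knockout and wild-type values did not overlap for any of the 214, and they did not overlap for 20.3% of all genes tested, where chance gives 10%. The count was 93 without WT 4, 83 without KO 2, 56 without KO 3 and 418 without KO 4, and 77 with no filter on low values. Weighting libraries by an estimated quality gave 3653 genes.

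Genes of cholesterol synthesis and uptake were higher in knockout. Of 19 tested members, 9 rose and none fell (15 and 0 adjusted over the list alone), all 19 had a positive log2 fold change, and the median was 0.65. Sqle, which encodes squalene epoxidase, went from 23.5 ± 1.37 to 47.7 ± 7.60 (log2 fold change 0.99 ± 0.13 SE), Mvd, of the mevalonate pathway, from 10.6 ± 1.09 to 20.7 ± 0.981 (0.93 ± 0.12 SE), and Fdps, which makes farnesyl pyrophosphate, from 31.7 ± 4.14 to 56.3 ± 5.92 (0.82 ± 0.13 SE). Fdft1, Insig1, Cyp51, Dhcr7 and Mvk were among the called members, of which Fdft1 and Insig1 lie in chromosome stretches rich in calls (below). The list passed in camera with a preset correlation (adjusted p = 7.62e-13, and 6.43e-05 or less in 17 alternatives) and not with an estimated one (adjusted p = 0.446). It held 4 calls without KO 2, 2 without KO 3 and 3 with no filter on low values. Sqle and Mvd kept their call without each library in turn, while Fdft1 and Fdps lost it without KO 3 (adjusted p = 0.0620 and 0.0766). Insig1 lost it without WT 4, KO 2 or KO 3 (at most 0.115), Cyp51 and Dhcr7 without WT 1, WT 3, KO 2 or KO 3 (at most 0.10 and 0.117), and Mvk without any library but WT 1 (at most 0.161) and after removal of GC and length trends (0.0545). With no filter on low values, Fdps (0.0687), Insig1 (0.0727), Cyp51 (0.0921), Dhcr7 (0.0841) and Mvk (0.0546) lost it as well, and Mvk also in voom (0.0503). In the same libraries dissociation and early response genes had a median log2 fold change of 0.19 (1 of 30 called, Hspa8, list adjusted p = 0.0432, and 0.766 with an estimated correlation).

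Part of the sinusoidal endothelial programme was lower. Of 18 tested genes on that list, 6 fell and none rose (9 lower and 1 higher adjusted over the list alone). Clec4g, a lectin of sinusoidal endothelium, fell from 1650 ± 132 to 698 ± 104 (log2 fold change -1.25 ± 0.12 SE). F8, the coagulation factor VIII gene, fell from 29.6 ± 5.31 to 14.1 ± 1.70, and Kitl, which encodes stem cell factor, from 67.7 ± 9.28 to 34.8 ± 6.14. Fcgr2b (above), Cd55, a complement regulator, and Tfpi, a coagulation inhibitor, were the other called members. Removal of GC and length trends (below) ended the calls of F8, whose log2 fold change went from -1.03 ± 0.16 SE to -0.53 ± 0.13 SE (adjusted p = 0.0914), and Tfpi, from -0.88 ± 0.17 SE to -0.52 ± 0.11 SE (0.0520). The list's adjusted p was 0.00367 in camera with a preset correlation, 0.446 with an estimated correlation and 0.0761 with quality weights, the highest of 17 alternatives. It held 2 calls without KO 3 and 1, Clec4g, with no filter on low values. Complement and coagulation genes overlapped this list, with 4 of 21 lower (F8, Cd55, Tfpi and Vwf, the gene of von Willebrand factor, at 2.0 ± 0.771 and 0.270 ± 0.230) and none higher (4 lower and 1 higher adjusted over the list alone). Their adjusted p was 0.0301, and 0.446 with an estimated correlation. Of 11 scavenger and endocytic receptor genes, Stab1, Fcgr2b and Clec4g fell and none rose (4 lower adjusted over the list alone), with an adjusted p of 0.0415 and one of 0.766 with an estimated correlation. That list's median was -0.053, its adjusted p was 0.538 once genes in chromosome stretches rich in calls, among them Stab1 and Fcgr2b, were left out, and 0.148 after removal of GC and length trends. Leaving out WT 1 or KO 4 ended the call of the complement and coagulation list (adjusted p = 0.0521 and 0.0571, and 0.00815 to 0.110 over 17 alternatives), and leaving out WT 3 or KO 4 that of the scavenger list (0.265 and 0.0708, and 0.00552 to 0.538 over the alternatives). The complement and coagulation list held 2 calls without WT 1 or WT 4, 1 without KO 2, 2 after removal of GC and length trends and 0 without KO 3 or with no filter on low values (6 of its genes at an unadjusted p under 0.05 with all libraries in limma). Single calls of F8 and Kitl were lost without WT 4 or KO 3 (at most 0.0620 and 0.0553), of Vwf without KO 2 or KO 3 (at most 0.0868), of Cd55 without WT 1, WT 3, KO 2 or KO 3 (at most 0.132) and of Tfpi without WT 1, WT 4, KO 2 or KO 3 (at most 0.153). With no filter on low values, F8 (0.0732), Kitl (0.0824), Cd55 (0.144), Tfpi (0.165) and Vwf (0.0902) all lost it. In the same libraries megakaryocyte markers had a median log2 fold change of -0.69 (1 of 17 called, list adjusted p = 8.29e-05, and 0.766 with an estimated correlation). Fcer1g, a macrophage marker that lies in a chromosome stretch rich in calls (below), fell, and dissociation and early response genes had a median of 0.19 (above).

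**Figure D2:**
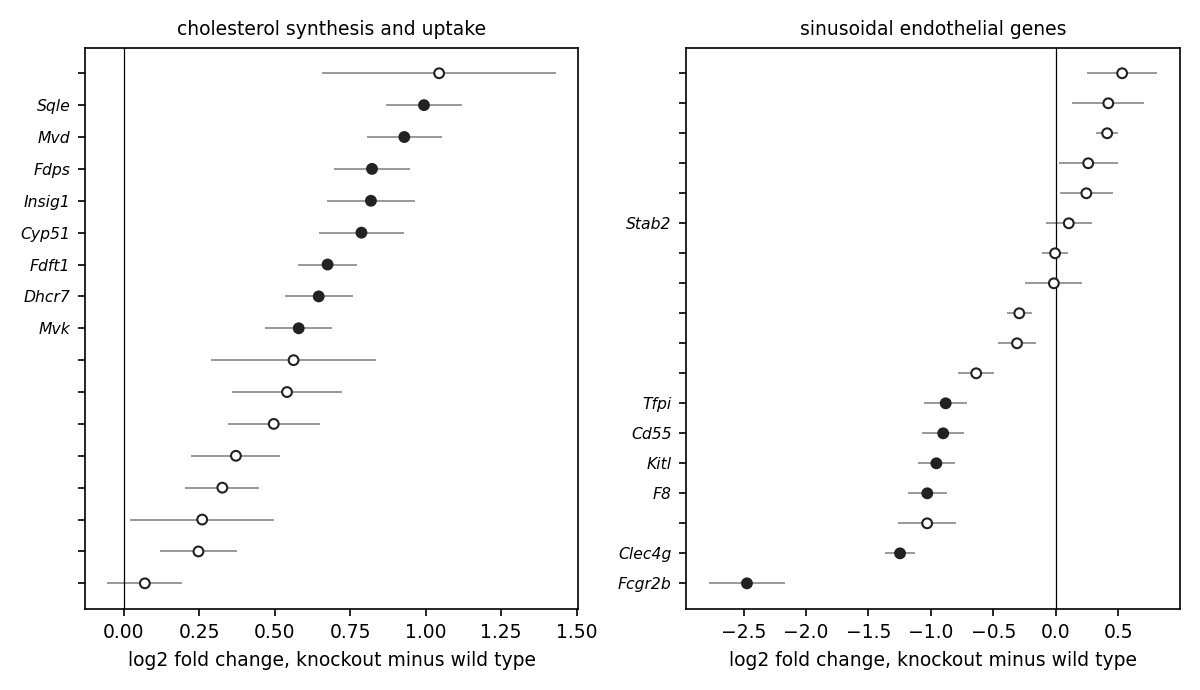
Log2 fold change (knockout minus wild type) with its standard error for tested genes of the cholesterol list (left, 17 genes drawn) and the sinusoidal endothelial list (right, all 18), where filled points passed an adjusted p of 0.05 and genes named in the text are labelled. All 17 cholesterol genes drawn lie above 0 and 8 are filled, and 6 sinusoidal genes are filled, all below 0.

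Since the study concerns contacts with lymphocytes, genes by which endothelium and stroma recruit them were examined. Cxcl13, the gene of the chemokine that draws B cells to follicles (chromosome 5, 95956939 to 95961068), fell from 62.4 ± 16.7 to 16.0 ± 2.70 (log2 fold change -1.91 ± 0.20 SE, adjusted p = 0.00159). It is made mainly by follicular reticular cells, and of the 19 tested reticular and fibroblast markers it was the only one called. Of these 19, 14 had a negative log2 fold change (median -0.32, list adjusted p = 0.0885, and 0.893 with an estimated correlation), and the list passed as lower without some libraries (below). The adhesion molecules did not pass. Madcam1 was at 7.37 ± 0.598 in wild type and 10.2 ± 4.41 in knockout (adjusted p = 0.586), Vcam1 at 173 ± 15.6 and 187 ± 21 (0.637), and Icam1 at 213 ± 39.3 and 224 ± 32.4 (0.819). Ccl19 was at 4.58 ± 2.10 and 5.05 ± 1.58 (0.812), and Ccl21a and its near-identical copies were listed at 0 in every library. Of 17 chemokine genes, 3 fell and none rose (7 and 0 adjusted over the list alone), namely Cxcl13, Pf4, the platelet chemokine, and Ccl6, a chemokine of myeloid cells. Cxcl13 and Pf4 lie on chromosome 5, itself rich in calls (28 of 705, odds ratio 2.25), though outside its enriched bin. Strain variants acting on nearby genes (below) thus stay open for both. The chemokine list had an adjusted p of 0.0222, and of 0.485 with an estimated correlation. Its call was lost without WT 1 (adjusted p = 0.228) or KO 4 (0.0571), with a 5 RPKM filter (0.148) and after removal of GC and length trends (0.0704). The range was 0.00172 to 0.255 in 17 alternatives, and the list held 1 called gene without KO 3 or with no filter on low values. Ccl6 lost its call without WT 4, KO 2 or KO 3 (at most 0.0843) and Pf4 without KO 3 (0.0772), and both with no filter on low values (0.0931 and 0.109). The medians of megakaryocyte markers and of dissociation and early response genes in these libraries (-0.69 and 0.19) are given above. Of 27 leukocyte adhesion genes 0 were called in limma (1 higher and 1 lower adjusted over the list alone, 8 at an unadjusted p under 0.05). Glycam1, a mucin ligand of L-selectin, was at 2.19, 0 and 0.0350 RPKM in WT 1, WT 3 and WT 4 and at 3.25, 11.4 and 4.74 in KO 2, KO 3 and KO 4 (adjusted p = 0.0596, and 0.00503 without WT 1).

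Markers of cells other than endothelium were measured in the same libraries. Megakaryocyte and platelet genes were lower in knockout as a list (median log2 fold change -0.69, adjusted p = 8.29e-05, and 0.766 with an estimated correlation), with 1 of 17 members called, Pf4 (3 lower adjusted over the list alone). Pf4 was at 52.3, 88.4 and 36.3 RPKM in WT 1, WT 3 and WT 4 and at 18.4, 15.4 and 19.2 in KO 2, KO 3 and KO 4. The call of Pf4 was lost without KO 3 (adjusted p = 0.0772), the list's median was -0.31 without WT 3, and the list did not pass with quality weights (adjusted p = 0.0934). Of 7 macrophage and monocyte markers, Fcer1g alone was called, falling from 224 ± 8.32 to 78.9 ± 31.5 (adjusted p = 0.00773, and 0.0793 with no filter on low values). Fcer1g lies in the stretch of chromosome 1 rich in calls (below), so its fall does not by itself measure macrophages. Uncalled members such as Lyz2, Tyrobp and Spic were at 13.6, 3.59 and 2.10 in wild type and 7.21, 2.41 and 1.57 in knockout. The macrophage list did not pass (1 lower adjusted over the list alone, adjusted p = 0.0508). It passed without WT 4 (0.00552), KO 2 (0.0486) or KO 3 (0.0232). It also did with a pseudocount of 1 (0.0465), quantile normalization (0.0480) or median centring (0.0416), and after removal of GC and length trends (0.0212), over a range up to 0.667 in 17 alternatives. The erythroid list did not pass either (0 of 9 called in limma or adjusted over the list alone, 1 at an unadjusted p under 0.05, adjusted p = 0.0543). It passed without WT 4 (0.000369) or KO 2 (3.19e-05), with no filter on low values (0.0458), with median centring (0.0416) and after removal of GC and length trends (0.0255), over a range up to 0.681. With quality weights its direction turned (median 0.30, adjusted p = 0.383). Its gene Car1 was at 39.2, 39.2 and 5.49 RPKM in WT 1, WT 3 and WT 4 and at 10.6, 1.36 and 0.510 in KO 2, KO 3 and KO 4. Car1 was not called (adjusted p = 0.157 in limma), but was without KO 2 (0.0446). Rgs5, a pericyte gene, fell from 6.56 ± 1.89 to 2.25 ± 0.537, as the 1 called gene of 16 smooth muscle and pericyte markers, also adjusted over the list alone. Its call was lost without WT 4, KO 2 or KO 3 (at most 0.0922) and with no filter on low values (0.103). Rgs5 lies beside the stretch of chromosome 1 rich in calls, at 169655501 to 169695813. The reticular (adjusted p = 0.0885), mesothelial (0.540), smooth muscle (0.660) and progenitor (0.346) lists did not pass. The reticular list did pass without WT 3 (0.00837), WT 4 (0.00552) or KO 2 (0.00530), and the mesothelial list without WT 3 (0.00480). However, the direction of the reticular list turned without WT 1 and with quality weights, and that of the mesothelial list without WT 1 and in voom. No more than 4 genes of the B, T, NK, plasma, dendritic, neutrophil and exocrine pancreas lists each were high enough to test, and 0 of those were called in limma, while 1 gene each of the B, T and dendritic lists was lower adjusted over the list alone. Ptprc, which encodes CD45, was at 0.110 RPKM or less in every library. Pan-endothelial genes included Pecam1 at 294 ± 28.5 and 344 ± 15.3 and Cldn5 at 1078 ± 33.9 and 1318 ± 65.6, with 0 of 24 called in limma or adjusted over the list alone, 4 at an unadjusted p under 0.05 (list adjusted p = 0.291).

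MHC class II genes passed as a list in the direction of higher values (median 0.61, adjusted p = 0.0222, and 0.766 with an estimated correlation), with 0 of 7 called in limma (3 adjusted over the list alone, 4 at an unadjusted p under 0.05). H2-Ab1, a class II beta chain gene, was at 31.4 ± 5.67 and 54.4 ± 14 (adjusted p = 0.0807, and 0.0481 without KO 4), and Cd74, the invariant chain gene, at 23.3 ± 15.0 and 41.4 ± 9.77 (0.230, and 0.00983 without WT 1). The list's call ended without WT 3 (adjusted p = 0.165) or WT 4 (0.0756), over a range of 0.000163 to 0.165 in 17 alternatives. Genes of tissue dissociation and early response also passed (median 0.19, adjusted p = 0.0432, and 0.766 with an estimated correlation). Their 1 called member of 30, also adjusted over the list alone, was Hspa8, a constitutive heat shock protein gene, at 74.4 ± 35.7 and 199 ± 9.09 (adjusted p = 0.0488). That list lost its call without WT 3 (0.249), WT 4 (0.115), KO 3 (0.134) or KO 4 (0.122), with a 5 RPKM filter (0.144) or quantile normalization (0.326) and after removal of GC and length trends (0.371), the highest of 17 alternatives. Hspa8 lost its call in 10 alternatives (at most 0.213), among them without KO 2 (0.118), KO 3 (0.167) or KO 4 (0.0847).

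The other 28 of the 36 lists tested did not pass, with adjusted p values of 0.0508 or more. No member was called in limma over all genes, nor adjusted over the list alone, for type I interferon response (1 of 28 at an unadjusted p under 0.05), interferon gamma (2 of 19), NF-kappaB targets (2 of 22), MHC class I (0 of 18), Notch (0 of 15), VEGF and angiogenesis (4 of 24), TGF-beta and BMP (4 of 26), cell cycle (2 of 28), lysosome (2 of 35), fatty acid handling (3 of 21), stabilin ligands (1 of 6), atypical chemokine and sphingolipid handling (2 of 15) and arterial identity (5 of 21). Also without a call over all genes, hypoxia and glycolysis held 1 gene higher adjusted over the list alone (5 of 22 at an unadjusted p under 0.05), basement membrane and matrix 2 higher and 2 lower (8 of 25), iron and haem 1 lower (1 of 15) and lymphatic identity 3 lower (3 of 8). Venous identity held 1 fall of 14 (Vwf), and Wnt and angiocrine factors 1 fall of 15 (Kitl), each also 1 lower adjusted over the list alone. Among these lists, leaving out 1 library made calls of cell cycle (adjusted p = 7.78e-10 without KO 2, against 0.291 with all), arterial identity (0.00107 without WT 1 and 0.0498 without KO 2, against 0.0885), NF-kappaB targets (0.0211 without WT 1, against 0.252), hypoxia (0.0314 without KO 4, against 0.0508, also 0.0354 with no filter on low values and 0.0452 with median centring) and type I interferon response (0.0413 without WT 3, against 0.554). The direction of the cell cycle list turned without KO 3 and with quality weights, and that of the type I interferon and interferon gamma lists without WT 4. After removal of GC and length trends, the reticular (adjusted p = 0.0430) and arterial (0.00230) lists passed. With quality weights, so did the type I interferon (0.00822) and interferon gamma (0.0102) lists. Of the 8 lists called, those of MHC class II, chemokines and complement (each 0.0547) and of scavenger receptors (0.101) were not called with no filter on low values, and quality weights ended every call but those of cholesterol and MHC class II. For the stabilin ligand, venous, VEGF and leukocyte adhesion lists the median, the mean and the direction of the test differed in sign.

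The called genes were placed on the GRCm38 annotation. Leaving out Stab1, 12 of 145 tested genes within 20 Mb of it were called (8.28%; 6 higher, 6 lower), against 184 of 10609 on the other chromosomes (1.73%), an odds ratio of 5.11 (95% interval 2.53 to 9.44, Fisher's exact test, two-sided p = 1.30e-05). On chromosome 14 as a whole, 28 of 365 were called, 19 higher and 9 lower. Among 10 Mb bins, the most called genes lay on chromosome 1 from 170 to 180 Mb, 13 of 59. It holds Ifi202b, Ifi204 and Mndal (a call lost without WT 4, KO 2 or KO 3, adjusted p at most 0.0763, and with no filter on low values, 0.0800), the Fc receptor genes Fcgr2b and Fcer1g, and Olfml2b, Pcp4l1 and Ppox. A bin of chromosome 13 from 60 to 70 Mb held 8 called genes of 39, among them Fbp1 and Zfp367, and one of chromosome 17 from 20 to 30 Mb held 10 zinc finger genes, all lower, whose similar sequences leave read assignment uncertain. After removal of GC and length trends that bin of chromosome 17 was no longer enriched, with 6 of 563 genes called on the chromosome against 14 before. Bins of chromosome 14 from 70 to 80 Mb (6 of 50 called) and of chromosome 19 from 40 to 50 Mb (8 of 89) and 60 to 70 Mb (3 of 9) were then enriched, and 22 of 405 genes were called on chromosome 19 against 12 before. Chromosome 14 held 29 calls with Stab1, and the 6 bins enriched in calls, some of them on that chromosome, held 52. With chromosome 14 and all 6 bins left out and the fit repeated on the other 10370 genes, 111 were called. The drop from 214 therefore includes calls outside these stretches that did not pass in the repeated fit.

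**Figure D3:**
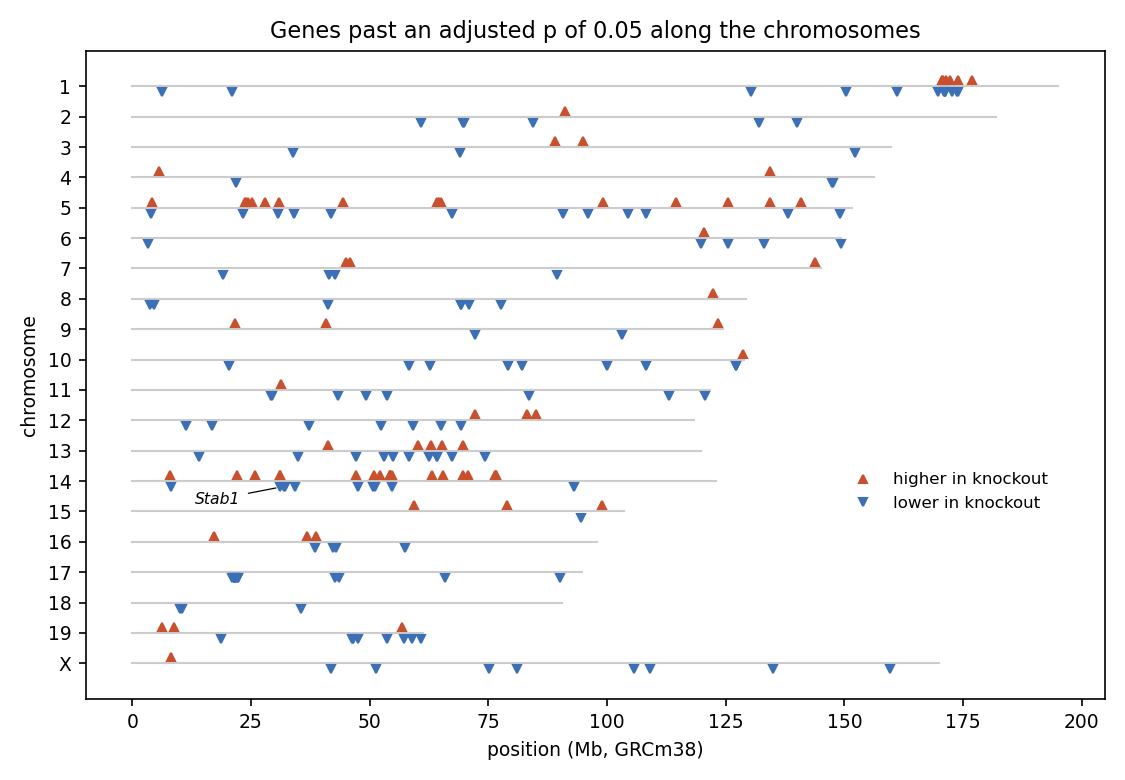
Start positions in Mb (GRCm38) of the called genes on each chromosome, drawn up to the last tested gene, with upward triangles for genes higher in knockout and downward triangles for genes lower in knockout. Calls crowd on chromosome 14, where Stab1 lies, and at the far end of chromosome 1, where 13 of 59 tested genes between 170 and 180 Mb were called.

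Fold change followed GC content. Across 10608 genes, which are not independent replicates, log2 fold change and transcript GC content had a Spearman correlation of 0.475, and lower genes had a median GC of 41.1% against 52.8% for higher genes and 50.3% for all genes tested. Per library, the correlation of deviations from the gene mean with GC was -0.262 in WT 1, -0.0475 in WT 3 and -0.533 in WT 4, and 0.467 in KO 2, 0.577 in KO 3 and -0.326 in KO 4. With each library's GC and length trend removed, 223 genes were called, 101 higher and 122 lower, of which 153 were among the 214. Among the named genes, F8 and Tfpi (above) were then no longer called, as their folds shrank. Mvk lost its call with a log2 fold change of 0.47 ± 0.10 SE, against 0.58 ± 0.11 SE before (adjusted p = 0.0545), and Hspa8 with a fold of nearly the same size (1.51 ± 0.35 SE, against 1.56 ± 0.33 SE; 0.0710).

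**Figure D4:**
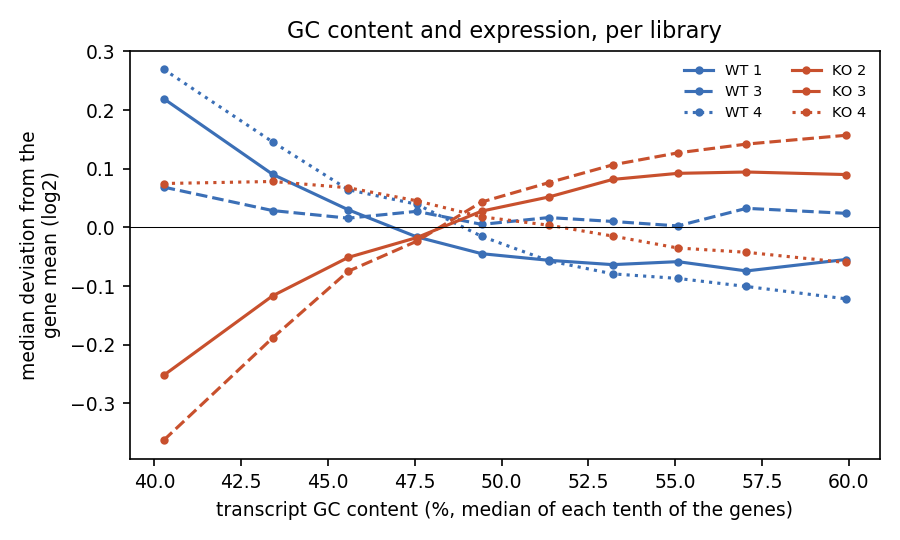
Median deviation from the gene mean (log2) in each of 10 equal groups of genes ordered by transcript GC content (%), one line per library, blue for wild type and red for knockout. KO 2 and KO 3 rise with GC content while KO 4 falls as WT 1 and WT 4 do.

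The authors' deposited comparison table was set beside these results. Of its 13742 genes, 216 had an adjusted p under 0.05, and the authors' deposited lists hold 34 higher and 117 lower genes, all with an adjusted p under 0.05 and at least a 2-fold change. Of those 151 genes, 128 were tested here, all 128 with the same direction, and 120 passed (28 higher, 92 lower). The number passing was 58 without WT 4, 59 without KO 2 and 44 without KO 3. Across the 11035 genes in both, log2 fold changes correlated at 0.968. In the authors' deposited table, Stab1 had a log2 fold change of -3.65 and an adjusted p of 0.000608.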

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

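The GC and length correction, voom on recovered reads, the removal of chromosome stretches rich in calls and the block on column numbers were chosen after seeing the data; the rest was planned. Against 214 genes called, 77 were with no filter on low values, where more genes were tested and entered the variance fit. There Stab1 kept its log2 fold change of -3.40, while its adjusted p in limma went from 7.15e-05 to 0.00748. The count was 117 with a 2-fold minimum and 111 without the stretches (fewer genes tested). It was 372 at an adjusted p of 0.1 and 3653 with quality weights. The weights put most of the fit on WT 4 (4.19) and KO 2 (3.12), and in other splits of the libraries, where the unweighted fit called 0, they called up to 851. Leaving out 1 library gave 56 to 418 genes. The GC correction moved the share of higher genes from 34.6% to 45.3%, and leaving out KO 4 moved it to 16.7%. Other pseudocounts, scalings, robust variances and voom gave 168 to 230. The 120 of the authors' listed genes that passed became 58 with no filter, 73 at a 5 RPKM minimum, 67 without the stretches and 44 to 119 without 1 library. The log2 fold change of Stab1 stayed between -3.66 and -3.16 without 1 library, and its exact permutation (-3.40, p = 0.1) cannot pass at this size. The 8 lists called became 0 with an estimated correlation, 0 in fry, 4 with quality weights and 5 to 13 without 1 library. Of 48 called genes named here besides Stab1, 29 kept their call without each library in turn, 20 lost it with no filter, and none changed direction in any setting run. Some settings let more or fewer genes or libraries enter, and the cause of a changed count or call was not tested in any setting. The column names share the numbers 3 and 4 between groups, which are not the labels' replicate numbers and are not known to pair libraries (deviations of same-numbered libraries correlated at 0.193 for each). A block on them, with 1 residual degree of freedom, called 355 genes and 13 lists. The planned count models and their scalings were set for deposited counts or reads recovered from CPM or RPM, so they were left out; only voom was run on the reads recovered from RPKM (219 genes). In simulation at these depths and this spread, 63.3% of 2-fold and 18.4% of 1.5-fold changes were called, so smaller changes can go uncalled.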

Other observations

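The GC and length correction was added after the data were seen, and the odds ratio near Stab1, the KO 4 trend, the chromosome 1 test without gene families, and the chromosome, cell type and dissociation tests of the cholesterol genes were chosen after the values they use had been seen. The count of 214 called genes compares with a highest count of 0 in the other 9 splits of the 6 libraries into 3 and 3, and 1 of 10 splits reached it. For gene lists, 7 of 10 splits called at least the 8 of the real split, and the highest other count was 12. As 10 splits cannot give a share under 0.05, the gene count cannot pass this test. The count of lists did not set the real split apart from the others.

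Called genes crowded along chromosomes, with 91 of 213 positioned calls having another within 1 Mb, against a mean of 63.3 in 10000 permutations (one-sided permutation p = 0.0008). GC content and length do not account for the excess near Stab1, since the odds ratio was 5.03 (95% interval 2.49 to 9.28) after their removal and 5.11 before. A candidate explanation is chromosome from a donor strain, carried along with the targeted allele, whose variants could alter expression or read mapping of neighbouring genes; the odds ratio of 5.11 is what this needs, but no strain variants were examined here, and an effect of the altered Stab1 locus on its neighbours stays open. At the end of chromosome 1, where 7 of 51 genes stayed called with gene families and pseudogenes left out (odds ratio 10.4, 95% interval 3.90 to 23.9), reads shared between paralogs do not account for the excess. Outside chromosome 14 as a whole, 69 calls had another within 1 Mb, against a mean of 50.6 (one-sided permutation p = 0.0108). With zinc finger and Ifi200 genes left out, the count was 47 against 40.3 (one-sided permutation p = 0.1933). As genes of these families lie side by side, leaving them out removes clusters of either origin. Outside chromosomes 1 and 14, this count therefore cannot tell shared reads from strain segments. One enriched bin there, on chromosome 5 from 20 to 30 Mb (6 of 49 called), holds no called gene of these families. On chromosome 1 strain segments stay open, as no strain variants were examined. For the zinc finger genes of chromosome 17, GC content and length stay open too, as their bin was no longer enriched after removal of those trends (6 of 563 genes called on the chromosome, against 14 before).

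Lower genes were poor in GC. Their median lay 9.20 points below that of all genes tested, and 2.11 points below after each library's GC and length trend was removed. That is just outside the 2 points set beforehand for a pure GC bias. The removal takes out a trend of any source, genotype included, so the distance left after it cannot tell a technical bias from genotype. After the removal, 88 of the 140 lower calls and 65 of the 74 higher calls remained. If loss of Stab1 alone made the trend, each knockout library should exceed the wild types in its correlation with GC, but the correlation in KO 4 (-0.326) lies below those in WT 3 (-0.0475) and WT 1 (-0.262). This is a single library, so library preparation and genotype cannot be told apart as sources of the trend.

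For the rise of cholesterol genes, the median log2 fold change was 0.58 after removal of GC and length trends (0.65 before, adjusted p = 4.22e-14 with a preset correlation), and 11 members were then called. Of the 9 members called, 7 lie outside chromosome 14 and the other stretches rich in calls. Of these, Cyp51 and Mvk lie on chromosome 5, itself rich in calls (28 of 705, odds ratio 2.25, Fisher's exact test, adjusted p = 0.00309). Position thus argues against strain variants acting on nearby genes for 5 members only, and it cannot test a variant that acts on genes elsewhere. For Fdft1, Insig1, Cyp51 and Mvk variants acting nearby stay open, as their chromosomes stayed rich in calls with cholesterol genes left out (odds ratio 2.09 or more). Of 7 tested lists of markers of other cell types, the highest median in the main fit was -0.069, for smooth muscle and pericytes. Over the alternatives the mesothelial median reached 1.16, against 0.43 to 0.71 for the cholesterol list, so mesothelial cells stay open. The highest of the others was 0.30 (erythroid), which argues against those types. Against leukocytes stand the CD45-negative sort and Ptprc, at 0.0259 to 0.0923 RPKM in knockout and 0.0618 to 0.110 in wild type. A single gene this low does not exclude them. What stays open is the genotype itself, untested apart from this comparison, and strain variants that act on genes elsewhere. Cells bearing MHC class II also stay open, as their list's median of 0.61 lies too near 0.65 to decide and endothelium expresses these genes too. So do cell types with too few tested markers, and stress of dissociation, whose list moved the same way but less (median 0.19). A shared variation between libraries stays open as well, with an estimated correlation of 0.315 among the cholesterol genes. The end of the list's call with an estimated correlation (adjusted p = 0.446) does not decide this. The complement and coagulation list, with an estimated correlation of -0.013, lost its call too. Its adjusted p was the same only through the adjustment over lists. Before adjustment, camera gave the cholesterol list 2.12e-14 with the preset and 0.0323 with the estimated correlation. For complement and coagulation these were 0.00502 and 0.0372. The equal adjusted values therefore do not speak against shared variation.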
